A study of Mus musculus with 9 samples.

How the data were processed

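RNA was measured in mouse KH2 embryonic stem cells grown with Lif on feeder cells, which were removed before RNA extraction. Per the labels, polyadenylated RNA was sequenced as strand-specific dUTP libraries from 3 groups of 3 biological replicates: wild type, CBFA2T2 knockout and PRDM14 knockout. The labels do not say whether the replicates were separate clones or separate cultures of the same cells, and they give no batch or date. Sample groups and replicate numbers were taken from the labels.

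The deposited values are raw counts per Ensembl gene, 1 library per file, with no normalization by the authors. The submitters' notes name Bowtie as the aligner, without a version, and mm9 as the genome. The gene coordinates in the files are those of GRCm38: of 32860 gene IDs found in GENCODE M21, all 32860 lay on the same chromosome and 25661 (78.1%) had the same start and end. The counting program, its strand setting and the annotation release are not given in the sources used here. Each of the 9 files held the same 33233 genes in the same order. For 27 genes the symbol was stored as a date and was restored through the Ensembl ID. There were 14 genes on chromosome Y and 0 mitochondrial genes. Gene coordinates below are those of the files (GRCm38).

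Total counts ranged from 10309196 (wild-type replicate 2) to 20129490 (CBFA2T2 knockout replicate 2), with 19389 to 21038 genes having a count. The 10 most abundant genes took 4.40% to 5.07% of the counts. Libraries of the same group differed by more than counting error, with a chi-square per degree of freedom of 3.18 to 20.08, so none was a copy of another. At these depths a gene at 1 CPM (count per 1000000 counts, here of the whole library without scaling) has between 10.3 and 20.1 counts per library. Reads carried no molecular identifiers, so counting error is a lower limit on the error.

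Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 16532. Libraries were scaled by TMM (factors 0.962 to 1.037), and a quasi-likelihood model with robust estimation was fitted to the 3 groups over all 9 libraries. The 3 comparisons were each knockout against wild type and the knockouts against each other. The tests were two-sided, and a gene was called when its p, adjusted by Benjamini-Hochberg over all genes of the comparison, was under 0.05. Log2 fold changes are given with a standard error, taken as their absolute value divided by the square root of the F statistic of the test. CPM are given as mean and SD of 3 libraries per group. They use the library size over the kept genes, multiplied by its TMM factor. Adjusted p values are those of edgeR unless another test is named. They measure the spread between these libraries only.

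In all, 25 lists of genes were written before the data were examined. They covered naive pluripotency, general pluripotency, the formative and primed state, primitive endoderm, trophectoderm, mesoderm and primitive streak, neural ectoderm, germline, DNA methylation, FGF/ERK signalling, Nodal/TGF-beta, BMP and ID genes, WNT targets, LIF/STAT3, polycomb, the MTG corepressor complex (the family of CBFA2T2), the PRDM family, the 2-cell-like state, feeder fibroblasts, p53 and apoptosis, the integrated stress response and amino acid genes, hypoxia and glycolysis, cell cycle, imprinted genes, and Y-linked genes. Of the listed genes, 16 were absent from the files, 10 of them 2-cell genes. Lists share some members, and Cbfa2t2 and Prdm14 were kept out of all of them. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 25 lists. Camera with an estimated correlation and fry were run beside it. Members were also counted with the p adjusted over the list alone.

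Genes were named by a rule written before the data were examined. It took the targeted genes, and the 10 largest rises and 10 largest falls of each knockout among called genes with a mean CPM of at least 5, a symbol that is not a gene model, and libraries of the groups compared that did not overlap. It also took up to 4 called members of each list by lowest adjusted p (or the member with the lowest p where none was called), and up to 5 genes per direction for the overlap of the knockouts and for the knockouts against each other. Pou5f1, Sox2, Nanog, Dnmt3b and Klf4 were named in each comparison whatever their values.

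Fold changes of both knockouts share the wild-type libraries. Their correlation and overlap were therefore set against 100 simulated pairs of unchanged groups with the same shared control. The alternatives tried were DESeq2 size factors, no filter on low counts, a mean CPM of at least 5, the DESeq2 1.42.0 Wald test, limma-voom, a fit on the compared groups alone, the replicate number as a block, an absolute log2 fold change of at least 1, split wild-type controls, and leaving out each library in turn. Added after the data were seen were a fit without the genes of chromosomes 6 and Y, leaving out libraries of the group not compared and, for single genes, a mean CPM of at least 5 and the fit on the compared groups alone.

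The pipeline was tested on simulated data with 200 changed genes. Changes of 1.5-fold were recovered for 37.3% to 50.7% of genes over the 3 comparisons, changes of 2-fold for 61.2% to 70.1%, and changes of 4-fold for 84.8% to 90.9%, all with the right sign. False calls were 3.5% to 8.5% of the calls. The moved list was called and 0 unmoved lists were. The simulated genes varied independently of each other, so this does not test list calls where members are correlated. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Isoforms, exons and sequence variants were not analysed here.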

Results

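CBFA2T2 is a co-repressor of the MTG family, and PRDM14 is a zinc-finger protein of pluripotent and germ cells. The libraries address how mouse embryonic stem cells change their RNA when either gene is disrupted. Cbfa2t2 (ENSMUSG00000038533, chromosome 2, 154436481 to 154539356) was at 99.2, 44.9 and 84.8 CPM in CBFA2T2 knockout replicates 1 to 3, and at 166, 160 and 177 CPM in the wild-type replicates. The libraries labelled PRDM14 knockout had 173, 158 and 146 CPM. The group means were 76.3 ± 28.1 in the CBFA2T2 knockout, 168 ± 8.69 in wild type and 159 ± 13.4 in the PRDM14-labelled group (CPM, SD, n = 3 each). Cbfa2t2 fell in the CBFA2T2 knockout (log2 fold change -1.14 ± 0.25 SE, adjusted p = 0.00753, or -0.86 without replicate 2) and was not called in the PRDM14-labelled libraries (-0.08 ± 0.24, adjusted p = 0.844).

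Prdm14 (ENSMUSG00000042414, chromosome 1, 13113457 to 13127163) was higher, not lower, in the libraries labelled PRDM14 knockout. Its CPM was 41.4, 42.2 and 63.5 in these replicates, 18.4, 14.6 and 15.0 in wild type, and 55.0, 56.3 and 67.6 in the CBFA2T2 knockout. The group means were 49.0 ± 12.5, 16.0 ± 2.12 and 59.6 ± 6.94 (CPM, SD, n = 3 each). Prdm14 rose in the PRDM14-labelled libraries (log2 fold change 1.61 ± 0.17, adjusted p = 3.46e-05) and in the CBFA2T2 knockout (1.89 ± 0.17, adjusted p = 6.83e-06). Counts per gene do not show which exons are present, so the RNA level neither shows nor rules out loss of the protein. Every comparison below rests on the labels, that of the CBFA2T2 knockout with wild type included, and the word knockout follows them.

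**Figure D1:**
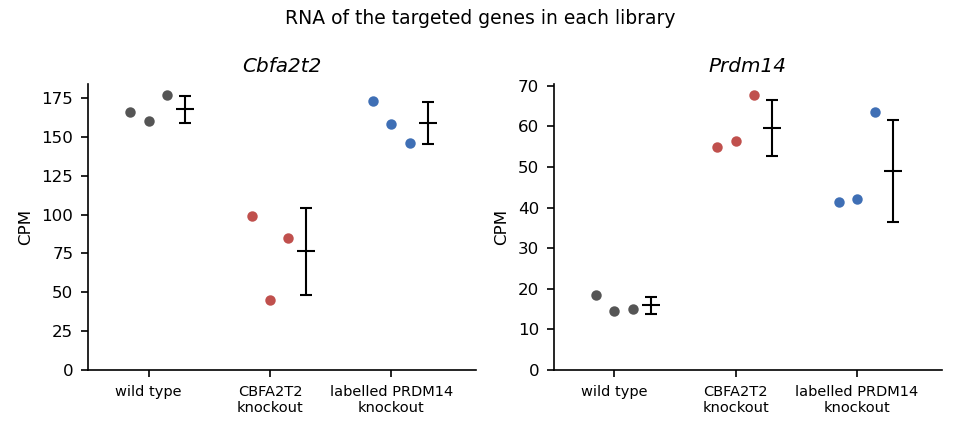
CPM of Cbfa2t2 and Prdm14 in each of the 9 libraries (points), with the mean and SD of each group (bar and whiskers, n = 3). Cbfa2t2 lay below 100 CPM in the CBFA2T2 knockout alone, and Prdm14 was lowest in wild type, at 14.6 to 18.4 CPM.

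In the CBFA2T2 knockout, RNA of the core pluripotency factors Pou5f1 and Sox2 fell while that of Nanog rose. Pou5f1 went from 757 ± 23.5 to 379 ± 36.0 CPM (log2 fold change -1.0 ± 0.08, adjusted p = 1.31e-06) and Sox2 fell by 0.78 ± 0.10 (log2, adjusted p = 4.31e-05). Nanog rose by 0.47 ± 0.11 (adjusted p = 0.00436), Klf4 fell by 0.64 ± 0.13 (adjusted p = 0.00288), and Dnmt3b fell by 1.45 ± 0.10 (adjusted p = 2.9e-07). Of 16532 genes tested, 6367 (38.5%) changed, 3127 up and 3240 down, and 1191 of the rises and 611 of the falls were at least 2-fold. The libraries of the 2 groups did not overlap for 53.7% of genes, where chance gives 10%.

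Rasgrp3, Krt8 and H19 were among the genes with the largest rises in the CBFA2T2 knockout. Rasgrp3 (ENSMUSG00000071042, chromosome 17, 75435905 to 75529043) went from 0.658 ± 0.328 to 20.1 ± 2.94 CPM (log2 fold change 4.99 ± 0.35, adjusted p = 4.73e-07). Krt8 (ENSMUSG00000049382, chromosome 15, 101996711 to 102004342) went from 22.3 ± 4.43 to 516 ± 276 CPM (4.52 ± 0.77, adjusted p = 0.00479), with 813 CPM in replicate 2 and 269 in replicate 3. The imprinted RNA H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143) went from 43.4 ± 11.1 to 825 ± 333 CPM (4.24 ± 0.39, adjusted p = 0.000213). Cxcl10 (4.86), Krt7 (4.61), Prox1 (4.59), Mogat2 (4.49), Zfp36l3 (3.98) and Ppp4r4 (3.84) were among the other large log2 rises. Cxcl10 was at 5.99 without wild-type replicate 3, and Zfp36l3 at 4.63 without wild-type replicate 1.

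Large falls in the CBFA2T2 knockout included Etv4, Etv1 and Spry4. Etv4 (ENSMUSG00000017724, chromosome 11, 101769742 to 101785371) went from 192 ± 11.3 to 3.84 ± 0.708 CPM (log2 fold change -5.66 ± 0.77, adjusted p = 0.00165). Etv1 fell by 4.0 ± 0.44 (log2, adjusted p = 3.75e-05), and Spry4 went from 131 ± 1.99 to 8.48 ± 1.90 CPM (-3.96 ± 0.39, adjusted p = 0.000189). Other large log2 falls were of Tgm3 (-4.76), Gna14 (-4.60), Col6a5 (-4.40), Pou4f2 (-4.40), Halr1 (-4.35) and Myo1f (-4.35). Without CBFA2T2 knockout replicate 1, Gna14 was at -6.43 and Pou4f2 at -5.09, and without replicate 2, Tgm3 was at -5.40 and Myo1f at -5.12.

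Of the 20 general pluripotency genes, 19 fell, 0 rose and 1 was not called in the CBFA2T2 knockout, with 20 falling when adjusted over the list alone. Trim28 (log2 fold change -0.96), Dppa4 (-1.92), Foxd3 (-3.24) and Phc1 (-1.74) had the lowest adjusted p. The list was called down by camera (adjusted p = 4.79e-16; adjusted p = 0.111 with an estimated correlation). Of 24 naive genes, 15 fell, 3 rose and 6 were not called, and 16 fell and 3 rose adjusted over the list alone. Nr0b1 (-2.38), Manba (-1.73) and Fgf4 (-1.18) fell. By camera the adjusted p was 3.1e-05, downward (adjusted p = 0.118 with an estimated correlation). Of 23 formative and primed genes, 12 fell, 7 rose and 4 were not called, and 13 fell and 7 rose adjusted over the list alone. Lef1 (-3.61), Dnmt3a (-1.98), Dnmt3b (-1.45) and Epha2 (-0.93) fell. The adjusted p of camera was 0.00675, downward (adjusted p = 0.118 with an estimated correlation). The calls in this list went both ways, so it did not move as a block.

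Most FGF/ERK genes fell in the CBFA2T2 knockout: of 22, 15 fell, 5 rose and 2 were not called, with the same counts of 15 and 5 adjusted over the list alone. Spred1 (log2 fold change -1.40), Ccnd1 (-1.07), Etv4 and Spry4 fell, while the receptors Fgfr1 (0.93) and Fgfr2 (1.97) rose. Egr1, of the same list, was also higher, at 427, 587 and 554 CPM against 139, 92.4 and 117 in wild type. Fgfr2 overlaps other annotated genes and is uncertain. Camera gave an adjusted p of 0.00178, downward (adjusted p = 0.289 with an estimated correlation). Of 14 DNA methylation genes, 7 fell, 3 rose and 4 were not called, with 8 falling and 3 rising adjusted over the list alone. Dnmt3a went from 469 to 119 CPM and Dnmt3b from 554 to 202 CPM, and Tet1 (-1.28) and Tet2 (-1.31) fell. Camera gave an adjusted p of 0.00201, downward (adjusted p = 0.237 with an estimated correlation). Of 20 polycomb genes, 10 fell, 2 rose and 8 were not called, with 12 falling and 2 rising adjusted over the list alone. Phc1 (-1.74), Jarid2 (-1.92), Eed (-0.81) and Kdm2b (-1.20) fell. The list had a camera adjusted p of 0.000871, downward (adjusted p = 0.118 with an estimated correlation).

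Trophectoderm and imprinted genes mostly rose in the CBFA2T2 knockout. Of 21 trophectoderm genes, 14 rose, 1 fell and 6 were not called, with the same 14 and 1 adjusted over the list alone. Krt7 (log2 fold change 4.61 ± 0.34), Esx1 (1.70 ± 0.18), Tfap2c (0.87 ± 0.10) and Fgfr2 (1.97 ± 0.13) had the lowest adjusted p, 2.36e-05 or lower. Camera gave an adjusted p of 1.41e-05, upward (adjusted p = 0.118 with an estimated correlation). Of 23 imprinted genes, 14 rose, 3 fell and 6 were not called, with 15 rising and 4 falling adjusted over the list alone. Plagl1 (2.68), Peg3 (1.68) and Impact (0.90) rose, and Grb10 fell (-1.89). The camera adjusted p was 0.00151, upward (adjusted p = 0.111 with an estimated correlation). Markers of feeder fibroblasts were higher in the same libraries: of 24, 11 rose, 0 fell and 13 were not called, with 12 rising adjusted over the list alone (camera adjusted p = 0.000578; adjusted p = 0.483 with an estimated correlation). The marker Tagln, which overlaps Pcsk7, was at 255, 333 and 127 CPM in CBFA2T2 knockout replicates 1, 2 and 3, where Krt8 was at 464, 813 and 269 CPM.

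Of 17 mesoderm and primitive streak genes, 7 rose, 2 fell and 8 were not called in the CBFA2T2 knockout, with 9 and 2 adjusted over the list alone. Wnt3 (log2 fold change 3.09), T (3.82), Snai1 (1.71) and Cdx1 (1.61) rose, and the camera adjusted p was 0.0219, upward (adjusted p = 0.118 with an estimated correlation). Of 23 primitive endoderm genes, 8 rose, 1 fell and 14 were not called, with the same 8 and 1 adjusted over the list alone. Gata4 (1.41), Serpinh1 (1.32), P4ha2 (0.85) and Col4a2 (1.81, which overlaps Col4a1) rose. The adjusted p of camera was 0.0192, upward (adjusted p = 0.499 with an estimated correlation), and 0.0726 without CBFA2T2 knockout replicate 1. Of 16 neural genes, 6 rose, 2 fell and 8 were not called, with 6 and 3 adjusted over the list alone. Nes (1.56), Ncam1 (0.87) and Lhx2 (2.11) rose and Pax6 fell (-3.02), and the list was not called (camera adjusted p = 0.185).

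Of 25 germline genes, 11 fell, 4 rose and 10 were not called in the CBFA2T2 knockout, with 11 falling and 5 rising adjusted over the list alone. Piwil2 (log2 fold change -1.80) and Tex11 (-2.13) fell, while Tfap2c (0.87) and Dppa3 (0.90) rose. The list had a camera adjusted p of 0.0551, downward. It was 0.031 without CBFA2T2 knockout replicate 3, and 0.0445, 0.0476 and 0.045 without wild-type replicates 1, 2 and 3.

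The PRDM14-labelled libraries showed a like picture against wild type, with fewer genes called. Pou5f1 went from 757 ± 23.5 to 434 ± 24.3 CPM (log2 fold change -0.80 ± 0.08, adjusted p = 9.48e-06), and Sox2 fell by 0.49 ± 0.10 (adjusted p = 0.00191). Dnmt3b fell by 1.37 ± 0.10 (adjusted p = 8.14e-07), and Nanog, on chromosome 6, rose by 0.75 ± 0.11 (adjusted p = 0.000235), or 0.73 without PRDM14-labelled replicate 1. Klf4 fell by 0.44 ± 0.13 (adjusted p = 0.0273). Its adjusted p rose to 0.103 and 0.108 without PRDM14-labelled replicates 2 and 3, and to 0.0967, 0.0549 and 0.0626 without wild-type replicates 1, 2 and 3. Of 16532 genes, 4941 (29.9%) changed, 2408 up and 2533 down, and 739 of the rises and 431 of the falls were at least 2-fold. The libraries did not overlap for 45.1% of genes, where chance gives 10%.

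**Figure D2:**
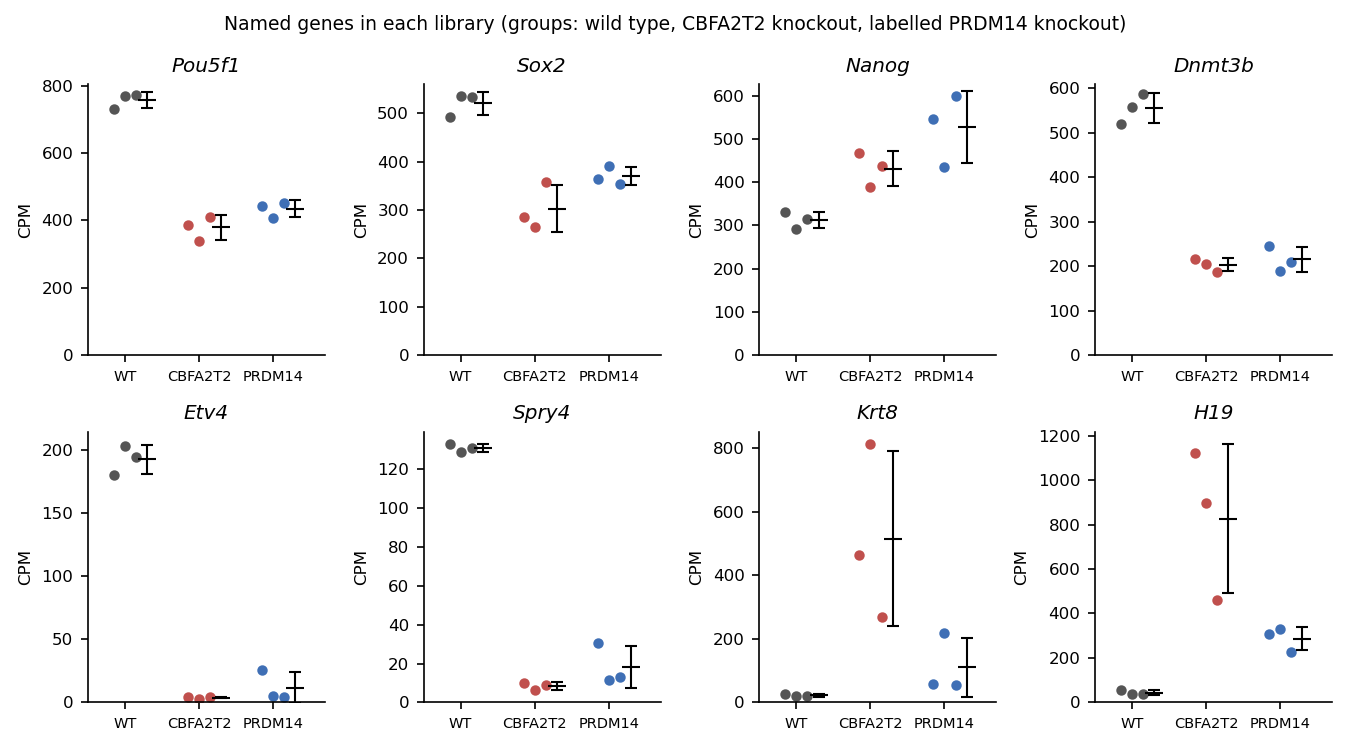
CPM of 8 named genes in each library (points), with the mean and SD of each group (bar and whiskers, n = 3). Pou5f1, Sox2, Dnmt3b, Etv4 and Spry4 were lower than wild type, and Nanog and H19 higher, in all libraries of both knockout groups.

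Large falls in the PRDM14-labelled libraries included several of the genes above. Etv4 went from 192 ± 11.3 to 11.6 ± 12.4 CPM (log2 fold change -4.04 ± 0.68, adjusted p = 0.0057), with 25.9 CPM in replicate 1 and 4.80 and 4.06 in the others, and was at log2 -5.43 without replicate 1. Lef1 (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356) went from 89.2 ± 12.2 to 7.88 ± 1.14 CPM (-3.50 ± 0.14, adjusted p = 8.56e-09). Pou4f2 (-3.69), Wt1 (-3.65), Tgm3 (-3.60), Col6a5 (-3.52), Myo1f (-3.30), Etv1 (-3.29) and Soga3 (-3.25) also fell, with Col6a5 at -4.45 and Etv1 at -4.23 without replicate 1. Among the rises, Flt1 (ENSMUSG00000029648, chromosome 5, 147561604 to 147726011) went from 5.72 ± 1.96 to 58.5 ± 3.96 CPM (3.32 ± 0.18, adjusted p = 1.62e-07). S100a13 (3.35), Ccdc80 (3.13), Copz2 (3.12) and S100a1 (3.11) also rose. The X-linked genes Xlr5a (4.31), Xlr5c (4.10), Xlr3c (3.49) and Xlr3a (3.33) are copies of a family with near-identical or overlapping genes, so their counts cannot be assigned with certainty. Without wild-type replicate 1, Xlr5a was at 5.64 and Xlr5c at 5.28.

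In the PRDM14-labelled libraries, 17 of 20 general pluripotency genes fell, 0 rose and 3 were not called, with 19 falling adjusted over the list alone. Dppa4, Lin28a, Trim28 and Jarid2 fell, by log2 -1.64, -0.97, -0.81 and -1.79. Camera gave an adjusted p of 7.94e-16, downward (adjusted p = 0.0857 with an estimated correlation). Of 24 naive genes, 11 fell, 6 rose and 7 were not called, with 12 and 6 adjusted over the list alone. Bmp4 (-3.13) fell while Tfcp2l1 (1.39) and Dppa3 (1.69) rose, so the list moved both ways. The adjusted p of camera was 0.0227, downward (adjusted p = 0.395 with an estimated correlation). Of 23 formative and primed genes, 14 fell, 2 rose and 7 were not called, with 14 falling and 4 rising adjusted over the list alone. Lef1 (-3.50), Dnmt3a (-1.87), Dnmt3b (-1.37) and Epha2 (-0.90) fell, and the camera adjusted p was 0.000139, downward (adjusted p = 0.0857 with an estimated correlation).

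Of 22 FGF/ERK genes, 14 fell, 4 rose and 4 were not called in the PRDM14-labelled libraries, with the same 14 and 4 adjusted over the list alone. Spred1 (log2 fold change -1.31) and Ccnd1 (-0.97) fell, and Egr1 (2.13) and Fgfr2 (1.59) rose, as did Fgfr1 (0.70), a gene named for the CBFA2T2 knockout. By camera the adjusted p was 0.000652, downward (adjusted p = 0.327 with an estimated correlation). Of 14 DNA methylation genes, 7 fell, 2 rose and 5 were not called, with 7 falling and 3 rising adjusted over the list alone. Dnmt3a and Dnmt3b fell to 129 and 215 CPM, and Mbd3 fell by 0.49 (log2). The camera adjusted p was 0.0149, downward (adjusted p = 0.395 with an estimated correlation). Of 20 polycomb genes, 10 fell, 3 rose and 7 were not called, with 10 and 4 adjusted over the list alone. Jarid2 (-1.79), Phc1 (-1.20) and Kdm2b (-1.11) fell, Ezh1 rose (0.70), and the camera adjusted p was 0.0138, downward (adjusted p = 0.327 with an estimated correlation).

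Of 21 trophectoderm genes, 8 rose, 0 fell and 13 were not called in the PRDM14-labelled libraries, with 10 rising adjusted over the list alone. Fgfr2 (log2 fold change 1.59), Krt7 (2.91), Esx1 (1.27) and Tfap2c (0.81) rose, and the camera adjusted p was 0.00508, upward (adjusted p = 0.327 with an estimated correlation). Krt8, named for the CBFA2T2 knockout, was not called (2.30 ± 0.72, adjusted p = 0.0572). Of 23 imprinted genes, 12 rose, 2 fell and 9 were not called, with 12 and 3 adjusted over the list alone. Plagl1 (2.52), Impact (1.05) and Peg3 (1.04) rose and Grb10 fell (-1.50). The list had a camera adjusted p of 0.00292, upward (adjusted p = 0.0857 with an estimated correlation). Of the 24 markers of feeder fibroblasts, 7 rose, 0 fell and 17 were not called, with the same 7 adjusted over the list alone (camera adjusted p = 0.00176; adjusted p = 0.541 with an estimated correlation). Tagln, named for the CBFA2T2 knockout too, was at 64.2, 193 and 77.4 CPM and Krt8 at 59.4, 218 and 55.5 CPM in PRDM14-labelled replicates 1, 2 and 3.

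The remaining lineage lists were not called in the PRDM14-labelled libraries. Of 17 mesoderm genes, 4 rose, 0 fell and 13 were not called, with the same 4 adjusted over the list alone (camera adjusted p = 0.2). Wnt3 (log2 fold change 2.43) and Cdx1 (1.90) rose. Snai1 (0.77) lost its call without PRDM14-labelled replicate 3 (0.49, adjusted p = 0.0926) and without wild-type replicates 2 and 3 (adjusted p = 0.0772 and 0.0618). T (2.01) lost its call without PRDM14-labelled replicate 2 (1.51, adjusted p = 0.0695). Of 23 primitive endoderm genes, 7 rose, 2 fell and 14 were not called, with the same 7 and 2 adjusted over the list alone. P4ha2 (1.14), Serpinh1 (1.03) and Gata4 (1.57) rose. Camera gave an adjusted p of 0.0715, and 0.0312, 0.0113 and 0.0372 without PRDM14-labelled replicates 2 and 3 and wild-type replicate 1. Of 16 neural genes, 4 rose, 4 fell and 8 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.652). Ncam1 (1.29) rose and Pax6 (-2.58) fell. Of 25 germline genes, 5 rose, 4 fell and 16 were not called, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.687). Dppa3 (1.69) rose and Piwil2 (-1.34) fell.

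Camera called 17 of the 25 lists in the CBFA2T2 knockout, 8 up and 9 down, and 13 in the PRDM14-labelled libraries, 5 up and 8 down. With an estimated correlation 0 lists were called in either comparison (9 and 4 at an unadjusted p under 0.05), while fry called 15 and 11. Of all genes tested 38.5% and 29.9% were called, against which the called members of each list are to be read.

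**Figure D3:**
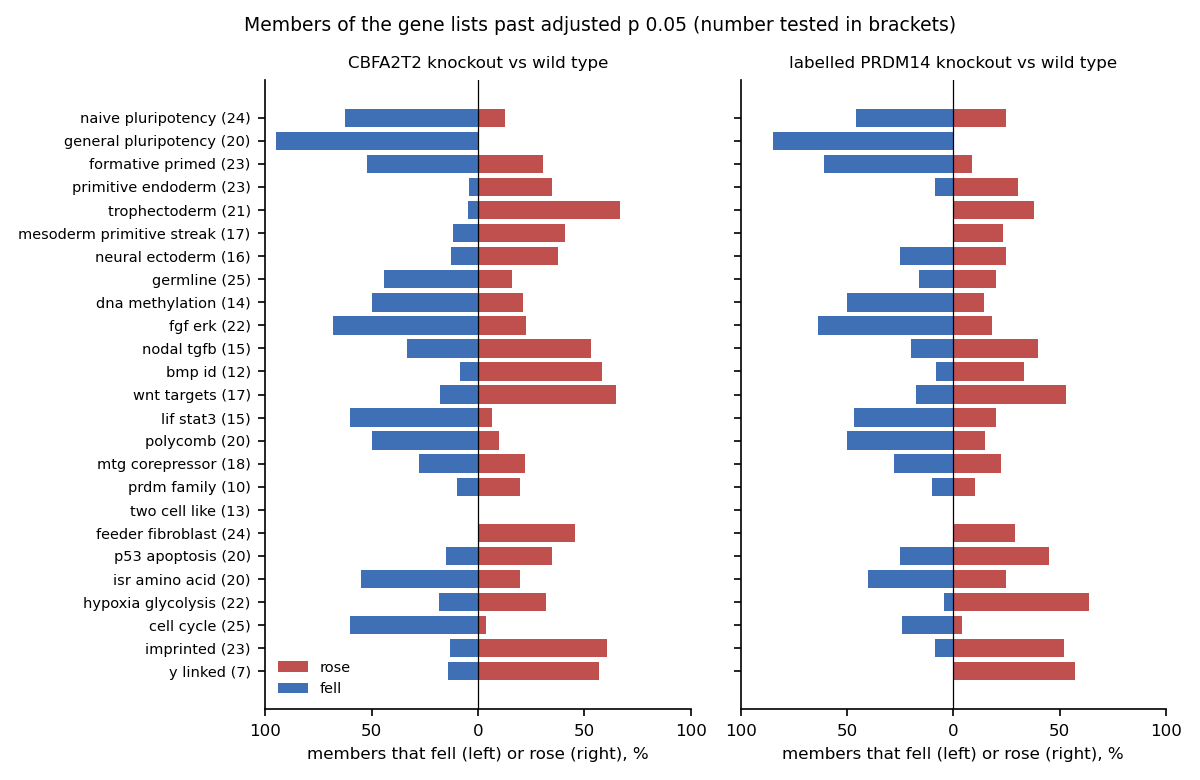
Share of the tested members of each of the 25 lists that rose (right) or fell (left) at an adjusted p under 0.05, in percent, in each knockout group against wild type. In general pluripotency 19 and 17 of 20 genes fell, and in trophectoderm 14 and 8 of 21 rose.

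The CBFA2T2 knockout and the PRDM14-labelled libraries shared most of their changes against the wild-type libraries. In both, Flt1 (log2 fold change 3.63 in the CBFA2T2 knockout and 3.32 in the PRDM14-labelled libraries), Efnb1 (2.75 and 2.26), Cldn4 (2.16 and 1.76), Taok3 (1.89 and 1.83) and Copz2 (3.30 and 3.12) rose. In both, Lef1 (-3.61 and -3.50), Dnmt3a (-1.98 and -1.87), Rarg (-1.81 and -1.72), Myrf (-3.38 and -3.17) and Fam169a (-1.73 and -1.50, overlapping Gm6169 and Nsa2) fell. Of the calls, 4159 went the same way in both (2000 up and 2159 down), which is 84.2% of the PRDM14-labelled calls and 65.3% of the CBFA2T2 calls. Only 3 genes, Tbx3, Pfkp and Gm7729, were called in opposite directions. Independent lists of the same sizes would share 455 rises and 496 falls.

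Across genes, which are not independent replicates, the fold changes of both knockouts had a Pearson correlation of 0.857 and a Spearman correlation of 0.814. Both comparisons use the same 3 wild-type libraries, and simulated unchanged groups with a shared control gave a mean correlation of 0.516 (0.484 to 0.55). The observed covariance was 0.445, against 0.0429 in the simulations, a difference of 0.402. The simulations called 0.03 genes the same way on average and 1 at most. With no group changed, almost no gene could be called in them, so this count does not measure sharing among called genes. Their genes also varied independently of each other, and their fit was made without robust estimation. With the wild-type libraries divided so that the knockouts shared no control, the correlation was 0.625 to 0.701. The slope of the PRDM14-labelled on the CBFA2T2 fold changes was 0.71. Any feature of these wild-type libraries appears in both comparisons, and no second set of wild-type libraries was analysed here.

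**Figure D4:**
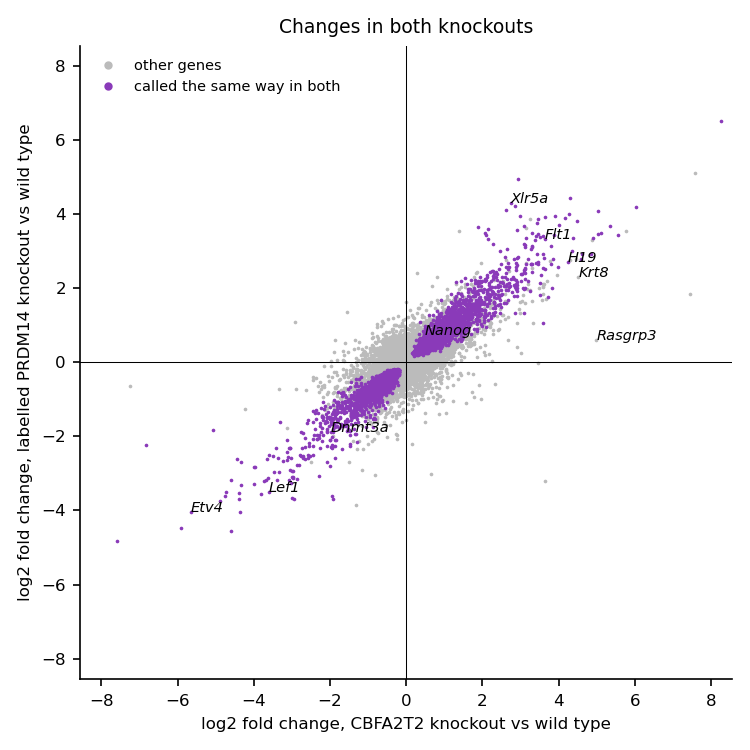
Log2 fold change against wild type of each of 16532 genes in the CBFA2T2 knockout (horizontal) and the PRDM14-labelled libraries (vertical), with the 4159 genes called the same way in both in purple and the others in grey. Most genes with large changes lay in the lower left and upper right, and Rasgrp3 rose in the CBFA2T2 knockout alone.

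Compared with each other, the knockout groups differed in 141 genes (0.9%), 56 higher and 85 lower in the CBFA2T2 knockout. Rasgrp3 was at 20.1 ± 2.94 CPM against 0.957 ± 0.527 in the PRDM14-labelled libraries (log2 fold change 4.40 ± 0.32, adjusted p = 3.37e-05). Lzts1 (1.99 ± 0.21, adjusted p = 0.00091) and Slc5a5 (1.72 ± 0.24, adjusted p = 0.00754) were also higher, and Nr0b1 was lower (-1.09 ± 0.13, adjusted p = 0.0018). Fam43b (1.77) lost its call without CBFA2T2 knockout replicate 1 or 2 (adjusted p = 0.0673 and 0.0518), as did Krt7 (1.69, adjusted p = 0.0806 and 0.0771). A2m, on chromosome 6, was lower (-1.78 ± 0.27, adjusted p = 0.0113). The pseudogene Cbfa2t2-ps1 was lower (-1.25 ± 0.21, adjusted p = 0.0148), but it can share reads with Cbfa2t2 and lost its call without CBFA2T2 knockout replicate 2 (adjusted p = 0.0862). Cbfa2t2 itself was at -1.06 ± 0.25 (adjusted p = 0.0975), and was called by DESeq2 (adjusted p = 0.0084), by limma-voom (0.0281) and with the replicate number as a block (0.0449). In the fit on the 2 groups alone Slc5a5, A2m and Cbfa2t2-ps1 lost their call (adjusted p = 0.0667, 0.0707 and 0.0898).

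The 141 genes depended on the method and on single libraries. There were 602 with DESeq2, 392 with the replicate number as a block, 328 with no filter on low counts, 24 in the fit on the 2 groups alone and 39 with an absolute log2 fold change of at least 1. The count was 34, 24 and 242 without CBFA2T2 knockout replicates 1, 2 and 3, 597 and 74 without PRDM14-labelled replicates 2 and 3, and 77, 45 and 56 without wild-type replicates 1, 2 and 3. Libraries of the groups did not overlap for 17.8% of genes, where chance gives 10%, and 2495 genes had an unadjusted p under 0.05. Pou5f1 (log2 fold change -0.20, adjusted p = 0.244), Sox2 (-0.29, adjusted p = 0.17), Nanog (-0.29, adjusted p = 0.215), Dnmt3b (-0.08, adjusted p = 0.733), Klf4 (-0.20, adjusted p = 0.524) and Prdm14 (0.28, adjusted p = 0.444) were not called.

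Naive pluripotency genes were lower in the CBFA2T2 knockout than in the PRDM14-labelled libraries: 7 of 24 fell, 0 rose and 17 were not called, with 11 falling adjusted over the list alone. Fgf4 (log2 fold change -0.79 ± 0.10), Nr5a2 (-0.77 ± 0.11) and Tfcp2l1 (-0.57 ± 0.08) had adjusted p values of 0.00214, 0.00631 and 0.00754. Camera called the list down (adjusted p = 4.67e-13), and the call held with an estimated correlation (adjusted p = 0.0382). The hypoxia and glycolysis list was also lower (camera adjusted p = 2.08e-13, and 0.0382 with an estimated correlation). Of its 22 genes, 2 fell (Pfkp, -0.74 ± 0.07, and Pgk1, -0.78), 0 rose and 20 were not called, with 13 falling adjusted over the list alone. Pgk1 lost its call without CBFA2T2 knockout replicate 1 or 2 (adjusted p = 0.0714 and 0.0631). In the integrated stress response list 1 of 20 fell (Nupr1, -0.81, adjusted p = 0.00631), 0 rose and 19 were not called, with 11 falling adjusted over the list alone (camera adjusted p = 3.6e-06, and 0.0411 with an estimated correlation). These 3 were the list calls between the knockouts that held with an estimated correlation. List calls between the knockouts were not tested on leaving out libraries, with another scaling or filter, or with the replicate block. Other splits of the libraries were not tried for them either. The gene calls of this comparison depended on single libraries, so how stable its list calls are is not known.

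The other camera calls between the knockouts did not hold with an estimated correlation. The CBFA2T2 knockout was higher in trophectoderm (1 of 21 rose, 8 adjusted over the list alone, camera adjusted p = 9.1e-09; adjusted p = 0.061 with an estimated correlation). It was lower in germline genes (2 of 25 fell, 7 adjusted over the list alone, camera adjusted p = 4.97e-05), with an adjusted p = 0.118 with an estimated correlation. The germline genes that fell were Kit (-0.64) and Dppa3 (-0.79). Both lost their call without CBFA2T2 knockout replicate 2 (adjusted p = 0.0518 and 0.122), and Dppa3 also without replicate 1 (adjusted p = 0.0775), and both in the fit on the 2 groups alone (adjusted p = 0.0667 and 0.0764). Dppa3 also lost it without wild-type replicate 2 (adjusted p = 0.0501). The WNT, BMP and ID, mesoderm, and formative lists were called up (camera adjusted p = 0.00146, 0.00257, 0.00495 and 0.0318), with adjusted p = 0.0903, 0.0698, 0.0707 and 0.159 with an estimated correlation. The general pluripotency, cell cycle, DNA methylation, polycomb and LIF/STAT3 lists were called down (camera adjusted p = 1.67e-05, 1.67e-05, 0.00144, 0.00205 and 0.00657), with adjusted p = 0.198, 0.266, 0.198, 0.128 and 0.308 with an estimated correlation. The remaining 11 lists were not called.

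Chromosome 6 genes were higher in 1 library, PRDM14-labelled replicate 1. Over 754 tested genes, their median log2 CPM against the other libraries was 0.43, while the medians of all other chromosomes and libraries lay between -0.08 and 0.08. Of the genes named above, Nanog, Halr1, A2m, Dppa3 and Phc1 lie on this chromosome. Without that replicate the PRDM14-labelled log2 fold change against wild type was 1.55 for Dppa3 and -1.36 for Phc1, and Dppa3 between the knockouts was at -0.66 (adjusted p = 0.0365). A2m was at 16.1 CPM in it, against 9.60 and 15.3 in the other PRDM14-labelled replicates.

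**Figure D5:**
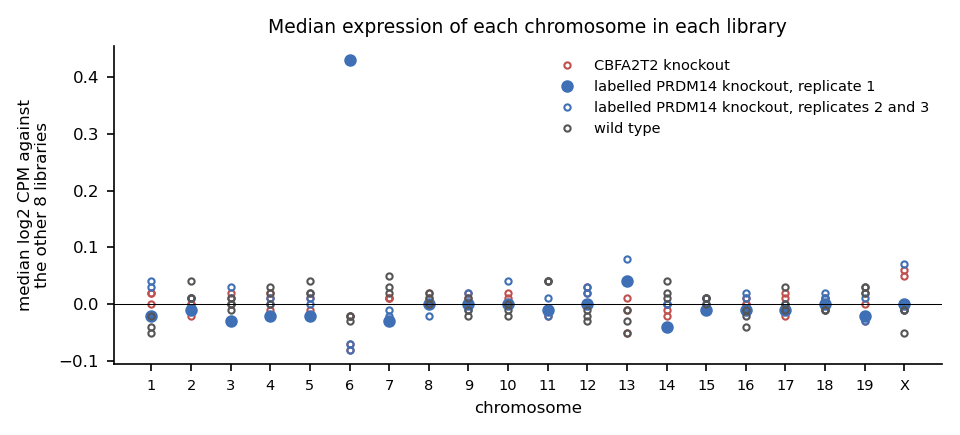
Median log2 CPM of the tested genes of each chromosome in each library, relative to the other 8 libraries (points, colored by group; filled points are PRDM14-labelled replicate 1). Chromosome 6 in that replicate, at 0.43, stood apart from all other points.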

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

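The tests of the chromosome 6, Y-linked and FGF/ERK patterns in this part, and the genes named for them outside the rule, were chosen after those patterns had been seen. In 3 genes the changes against the wild-type libraries went in opposite directions in the CBFA2T2 knockout and the PRDM14-labelled libraries, and the 2 groups differed by the edgeR test. Tbx3 was lower in the CBFA2T2 knockout (log2 fold change against wild type -0.24, adjusted p = 0.0492) and higher in the PRDM14-labelled libraries (0.34, adjusted p = 0.0107), a difference of -0.58 ± 0.09 (adjusted p = 0.0103). Pfkp, which overlaps Pitrm1, moved by -0.42 (adjusted p = 0.000373) and 0.33 (adjusted p = 0.00289), a difference of -0.74 ± 0.07 (adjusted p = 0.000237). The gene model Gm7729 moved by -0.44 (adjusted p = 0.0305) and 0.40 (adjusted p = 0.0474), a difference of -0.84 ± 0.14 (adjusted p = 0.0188). No explanation of these 3 was tested.

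Of 22 FGF/ERK genes 15 and 14 fell, and 5 and 4 rose, in the CBFA2T2 knockout and the PRDM14-labelled libraries. Dnmt3a and Dnmt3b fell in both, whereas PRDM14 is known to repress Dnmt3a, Dnmt3b and FGF receptor signalling in mouse embryonic stem cells. Fgfr1 (log2 fold change 0.93 and 0.70) and Fgfr2 (1.97 and 1.59, overlapping other genes) rose in both, as loss of that repression would give for these 2 receptors. Other FGF receptors were not set beside them here. Dilution by RNA of the feeders, which were removed before extraction, is excluded as the whole cause, since it would lower all stem cell genes. Against that, 3 naive genes were called higher in the CBFA2T2 knockout (Tfcp2l1, Dppa3 and Nanog). A partial contribution remains open: 11 and 7 of 24 feeder genes rose and 0 fell. Among all 16532 genes tested, 3127 and 2408 rose, a smaller share in each comparison. Col1a1 went from 98.8 to 374 and 382 CPM, while Col3a1 (0.17 and 0.22), Dcn (-0.20 and -0.10) and Mmp2 (0.13 and 0.13) were not called. Labels exchanged between the wild-type and PRDM14-labelled libraries could give the falls. The rises of Fgfr1 and Fgfr2 go the other way, but they are 2 receptors alone and Fgfr2 is uncertain. They do not decide against an exchange. The higher Prdm14 RNA (log2 fold change 1.61) lies in the direction that an exchange would give. In the CBFA2T2 knockout, where Prdm14 was not the labelled target, it was also above wild type (1.89). These values do not decide the question, since a knockout allele can leave its RNA in place, although that alone gives no rise. An exchange of labels therefore remains open. If the labels were exchanged, the 6367 genes would set the CBFA2T2 knockout against PRDM14 knockout and the 141 against wild type. A difference of the wild-type cultures unrelated to genotype, and an effect of the genotypes themselves, which the design names, remain open too: 84.2% of the PRDM14-labelled calls were shared with the CBFA2T2 knockout, and both rest on the same wild-type libraries.

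An extra copy of chromosome 6 in part or most of the cells may explain its higher median in PRDM14-labelled replicate 1. In all 13 stretches of 10 Mb with at least 20 tested genes the median was above 0, from 0.28 to 0.62, where 3 copies in place of 2 in every cell would give 0.58 on the log2 scale. A few abundant genes are excluded, since 83.4% of the chromosome 6 genes were above the other libraries there, against 38.3% to 47.9% in each of the others. The design gives no biological group to set against it, so no biological explanation was tested.

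The Y-linked genes Ddx3y (log2 fold change 1.29 ± 0.21 in the CBFA2T2 knockout and 1.68 ± 0.21 in the PRDM14-labelled libraries), Uty (1.94 ± 0.32 and 2.30 ± 0.32), Eif2s3y (2.50 ± 0.49 and 2.64 ± 0.49) and Kdm5d (3.08 ± 0.71 and 3.19 ± 0.71) were higher than in wild type, while Usp9y fell in the CBFA2T2 knockout (-2.09 ± 0.64); without PRDM14-labelled replicate 3, the highest in all 4, the PRDM14-labelled values were 1.37, 1.85, 2.0 and 2.24, all still called. More reads from a rise of the X-linked homologues are excluded, since the highest log2 fold change of Kdm6a, Ddx3x, Kdm5c and Eif2s3x was -0.08. Ddx3x (-0.53 and -0.49), Kdm5c (-0.34 and -0.28) and Kdm6a (-0.30 and -0.38) were called lower in both comparisons. The test could register only a rise, so shared reads as such are not excluded. Fewer cells with a Y chromosome in the wild-type cultures could lower these genes by a common factor. Their log2 fold changes spanned 1.79 in the CBFA2T2 knockout, but homologous reads set an unknown floor, and the low counts of Usp9y decide nothing. The genotypes and this explanation cannot be told apart here.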

How the results depend on the processing

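The fits without the genes of chromosomes 6 and Y, and those without a library of the group not compared, were chosen after seeing the data, as were, for single genes, a mean CPM of at least 5 and the fit on the compared groups alone; the other alternatives were chosen before the data were examined. The CBFA2T2 knockout against wild type gave 4800 to 7144 genes over all alternatives except the limit of log2 1 (4800 to 5811 leaving out each library of its groups), and the PRDM14-labelled libraries gave 3386 to 5164 (3386 to 4970 leaving out each library). With an absolute log2 fold change of at least 1 the counts were 1802, 1170 and 39 for the 3 comparisons, since that limit only removes genes. The 141 genes between the knockouts became 328 with no filter on low counts, 602 with DESeq2, 24 in the fit on the compared groups alone, and 392 with the replicate number as a block, and 24 to 597 leaving out each library; the cause was not tested. Of the 141, 22 were called in the fit on the compared groups alone and 139 by DESeq2. Without the genes of chromosomes 6 and Y the counts were 6202, 4844 and 177, and without PRDM14-labelled replicate 1 the CBFA2T2 comparison gave 6829 genes and 17 lists. Cbfa2t2 stayed lower (log2 -1.37 to -0.86 leaving out each library) and Prdm14 higher (1.38 to 1.73), and both stayed called under every alternative tried for them, with an adjusted p of 0.0466 for Cbfa2t2 in the fit on the compared groups alone.

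With an estimated correlation 0 lists were called in either comparison with wild type, and the cause was not tested; otherwise 15 to 19 and 11 to 15 lists were called. The correlation of fold changes was 0.65 with no filter, 0.906 at a mean CPM of at least 5, and 0.782 to 0.869 leaving out each library. With 1 wild-type library for 1 knockout and the other 2 for the other it was 0.648, 0.683 and 0.701 when replicate 1, 2 or 3 alone served the CBFA2T2 knockout, and 0.625, 0.676 and 0.695 when it served the PRDM14-labelled group. Genes called the same way numbered 2852 to 4289. Of the named genes, 120, 113 and 45 in the 3 comparisons, 2, 6 and 13 lost their call on leaving out a library of the groups compared, 1, 1 and 7 on leaving out one of the third group, and 0 reversed. Under the other alternatives, the log2 limit apart, 0, 0 and 13 lost it: between the knockouts 13 of 24 calls in the fit on the compared groups alone and 2 at a mean CPM of at least 5. That filter removed 9, 6 and 1 called genes, and leaving out chromosomes 6 and Y 9, 8 and 2. Residuals of libraries of different groups with the same replicate number correlated by -0.01 to 0.30, and those with different numbers by -0.21 to 0.06. Of the same-number pairs 2 of 9 were above 0.1, short of the rule that every pair be above it. The numbers were therefore not used as pairs. As a hint from the data of a shared structure, 8 of 9 libraries correlated best with their own number, and with the replicate block the counts were 6556, 5123 and 392. At this depth and number of libraries, simulated 1.5-fold changes were found in 37.3% to 50.7% of genes. The part of depth alone was not tested. The simulation changed far fewer genes than were called against wild type. With more changed genes the adjustment is less strict, so these shares do not give the sensitivity of the comparisons with wild type.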

Other observations

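The counts of gene calls over other splits of the libraries were chosen after the real counts had been seen, and those of list calls before. Of 17 WNT targets, 11 rose, 3 fell and 3 were not called in the CBFA2T2 knockout, with the same 11 and 3 adjusted over the list alone. Wnt3 (log2 fold change 3.09) rose, and Lef1 (-3.61), Ccnd1 (-1.07) and Notum (-1.86) fell. By camera the adjusted p was 0.0219, upward (adjusted p = 0.228 with an estimated correlation), and 0.0604 without wild-type replicate 1. The PRDM14-labelled counts were 9 up, 3 down and 5 not called, with 11 and 3 adjusted over the list alone (camera adjusted p = 0.16). There the list median was 1.22 and the camera direction upward, while fry gave the opposite sign. Of 12 BMP and ID genes, 7 rose, 1 fell and 4 were not called in the CBFA2T2 knockout, with the same 7 and 1 adjusted over the list alone. Id4 (2.42), Bmp7 (2.51) and Id3 (1.97) rose and Bmp4 fell (-2.97), with a camera adjusted p of 0.0159 (adjusted p = 0.118 with an estimated correlation). Against wild type, 4 rose, 1 fell and 7 were not called in the PRDM14-labelled libraries, with the same counts adjusted over the list alone (camera adjusted p = 0.108). Of 15 Nodal/TGF-beta genes, 8 rose, 5 fell and 2 were not called in the CBFA2T2 knockout, with the same 8 and 5 adjusted over the list alone (camera adjusted p = 0.37). In the PRDM14-labelled libraries 6 rose, 3 fell and 6 were not called, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.459). Lefty1 (1.96 and 1.30) rose and Inhbb (-2.52 and -2.52) fell in both. Of 15 LIF/STAT3 genes, 9 fell, 1 rose and 5 were not called in the CBFA2T2 knockout, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.37 with an estimated correlation). The PRDM14-labelled counts were 7 down, 3 up and 5 not called, with 8 and 3 adjusted over the list alone. The adjusted p of camera was 0.0227, downward (adjusted p = 0.462 with an estimated correlation), and 0.0658 without PRDM14-labelled replicate 3. Lifr (-1.69 and -1.07) and Klf5 (-1.58 and -1.35) fell and Tfcp2l1 (0.81 and 1.39) rose in both.

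Of 22 hypoxia and glycolysis genes, 14 rose, 1 fell and 7 were not called in the PRDM14-labelled libraries, with the same 14 and 1 adjusted over the list alone (camera adjusted p = 3.35e-06, upward; adjusted p = 0.111 with an estimated correlation). P4ha1 (log2 fold change 1.32), Bnip3 (1.02), Ero1l (1.09) and Aldoa (0.62) rose. In the CBFA2T2 knockout 7 rose, 4 fell and 11 were not called, with 8 and 5 adjusted over the list alone (camera adjusted p = 0.178). Of 20 integrated stress response genes, 11 fell, 4 rose and 5 were not called in the CBFA2T2 knockout, with 12 and 5 adjusted over the list alone (camera adjusted p = 0.00675; adjusted p = 0.118 with an estimated correlation). Chac1 (-2.08), Slc7a5 (-0.90) and Shmt2 (-0.72, overlapping Ndufa4l2) fell and Ddit4 (1.10) rose. Against wild type, 8 fell, 5 rose and 7 were not called in the PRDM14-labelled libraries, with 9 and 5 adjusted over the list alone (camera adjusted p = 0.233). Of 25 cell cycle genes, 15 fell, 1 rose and 9 were not called in the CBFA2T2 knockout, with 16 and 1 adjusted over the list alone (camera adjusted p = 7.72e-05; adjusted p = 0.321 with an estimated correlation). In the PRDM14-labelled libraries 6 fell, 1 rose and 18 were not called, with the same 6 and 1 adjusted over the list alone. The camera adjusted p was 0.0212 (adjusted p = 0.541 with an estimated correlation), and 0.106 without PRDM14-labelled replicate 2. Ccne1 (-1.47 and -1.16) and Cdc20 (-0.66 and -0.67) fell in both. Of 20 p53 genes, 7 rose, 3 fell and 10 were not called in the CBFA2T2 knockout, with 8 and 3 adjusted over the list alone. Camera gave an adjusted p of 0.069, and 0.0109 without CBFA2T2 knockout replicate 3. The PRDM14-labelled counts were 9 up, 5 down and 6 not called, with the same counts adjusted over the list alone. By camera the adjusted p was 0.13, and 0.0365 without PRDM14-labelled replicate 3. Cdkn1a (1.45 and 1.40) and Ccng1 (0.60 and 0.55) rose and Sesn2 (-0.55 and -0.35) fell in both.

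The MTG corepressor and PRDM families showed no common direction. Of 18 corepressor genes, 4 rose, 5 fell and 9 were not called in both comparisons, with 5 and 5 in the CBFA2T2 knockout and 4 and 5 in the PRDM14-labelled libraries adjusted over the list alone (camera adjusted p = 0.695 and 0.59). Sin3a (log2 fold change -0.66 and -0.55) fell and Sin3b (0.57 and 0.36) rose in both. The list means were 0.16 and 0.13 while the medians were -0.07 and -0.03 and the test direction was down. Of 10 PRDM genes, 2 rose, 1 fell and 7 were not called in the CBFA2T2 knockout, with 1 and 1 adjusted over the list alone, and 1 rose, 1 fell and 8 were not called in the PRDM14-labelled libraries, with 1 and 1 adjusted over the list alone (camera adjusted p = 0.663 and 0.762). Here too the means (0.12 and 0.10) and the medians (-0.14 and -0.08) differed in sign, and the test direction was down. Prdm1 (1.14 and 1.00) rose in both. Of 13 genes of the 2-cell-like list, 0 rose, 0 fell and 13 were not called by edgeR in either comparison, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. DESeq2 called 0 in either, and limma-voom 0 in the CBFA2T2 knockout and 1, Sp110, in the PRDM14-labelled libraries. The adjusted p of camera was 0.37 in the CBFA2T2 knockout. It was 0.0581 in the PRDM14-labelled libraries, 8.77e-05 without PRDM14-labelled replicate 3 and 0.0315 without wild-type replicate 2. The member with the lowest p, Gm5662, was at -0.51 (adjusted p = 0.23) and -0.39 (adjusted p = 0.381).

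Of the feeder fibroblast genes, Lox (log2 fold change 2.27 and 2.46) and Cdkn2a (0.86 and 0.73) rose in both, and Tagln (3.63 and 2.53) overlaps Pcsk7. Of genes chosen after their values were seen, Col1a1 went from 98.8 CPM in wild type to 374 and 382 CPM, and Col3a1 (0.17 and 0.22), Dcn (-0.20 and -0.10) and Mmp2 (0.13 and 0.13) were not called. Of 7 Y-linked genes, 4 rose, 1 fell and 2 were not called in the CBFA2T2 knockout, with the same 4 and 1 adjusted over the list alone (camera adjusted p = 0.0208; adjusted p = 0.483 with an estimated correlation). In the PRDM14-labelled libraries 4 rose, 0 fell and 3 were not called, with 6 rising adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.499 with an estimated correlation). Zfy1, chosen after its values were seen, had 0.991, 9.23 and 42.9 CPM in PRDM14-labelled replicates 1, 2 and 3, or 17, 152 and 686 counts. The median log2 fold change of 934 X-linked genes was 0.05, 0.04 and 0.01 in the CBFA2T2 knockout, in the PRDM14-labelled libraries and between the knockouts, against 0.00, 0.02 and 0.00 for autosomal genes.

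Among the genes between the knockouts, a feature chosen after the values were seen was the share of pseudogenes and gene models. Of the 85 lower genes, 35 had the symbol of a pseudogene or gene model, as had 6 of the 56 higher genes and 16.2% of all genes tested. Rps6-ps2 (log2 fold change -1.21 ± 0.24, adjusted p = 0.0342) and Rpl27-ps3 (-1.12 ± 0.21, adjusted p = 0.0318) were among them. Reads of such genes and their parent genes are hard to tell apart. Both lost their call without CBFA2T2 knockout replicate 1 (adjusted p = 0.146 and 0.135) or 2 (0.159 and 0.123), or PRDM14-labelled replicate 3 (0.0951 each), and in the fit on the 2 groups alone (0.119 and 0.108). The same held without wild-type replicate 2 (adjusted p = 0.0727 and 0.0603) or 3 (0.0652 and 0.0631).

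For each comparison of 6 libraries there are 10 splits into 3 against 3, which are too few for a share under 0.05. The real split gave 6367, 4941 and 141 genes, and the highest other split 0, 0 and 5. For lists, the real split gave 17 in the CBFA2T2 knockout and 13 in the PRDM14-labelled libraries, and the highest other split 14 and 10. In each case 1 split, the real one, gave a result as large. Splits of mixed groups thus also called many lists by camera with the preset correlation. In such splits a difference between the groups enters the spread and lowers the gene count. Part of that difference also remains and can move lists. The other splits therefore do not show what either count would be without a difference.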
